A study of Homo sapiens with 16 samples.

How the data were processed

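Bulk RNA sequencing had been done on cultured human brain vascular pericytes, the contractile mural cells that wrap capillaries. The labels describe 16 libraries in 4 groups of 4. Cells received either a scrambled control siRNA (Scr) or an siRNA against ALK5 (siALK5), the type I receptor of transforming growth factor β, whose gene is TGFBR1. Each arm was then either left untreated or given TGFβ1. Per the labels, the siRNA was used at 50 nM for 6 h and the cells recovered for 36 h. TGFβ1 was added at 5 ng/mL for 12 h after 24 h in 1% serum. The labels give this serum step for both TGFβ1-treated groups and do not say whether untreated cells had it. An effect of serum that is alike in both arms cancels in the difference in response, and 1 that depends on ALK5 does not. RNA had an integrity number above 9, and poly(A) libraries were made from 200 ng of RNA. Nothing in the labels says whether replicates came from separate cultures or donors. P-values of single genes thus measure only the spread between these samples, which may be technical. P-values of lists and families of genes set the members against other genes and do not measure that spread.

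The deposited files hold 5 tables, 1 for each of 4 pairs of groups and 1 that sets the other groups against Scr untreated, and no column for a single sample. Per the submitters' processing notes, the authors used Partek, Bowtie2 and DESeq2 with build hg19, and no versions, settings or order of steps are given. Each deposited table gives a total count per gene, a p-value, a step-up false discovery rate (printed here as the adjusted p) and a signed fold change per comparison, all made by the authors. The total of a gene was the same in all 5 tables and was not a whole number, so it stands for scaled or estimated counts. The totals summed to 361617246, which would be 22601078 per library if spread over 16 libraries. The depth of each sample is not given in the files and is unknown, so no range of counts per sample could be given. FN1 held 2.74% of the total, the 10 largest genes together held 11.1%, and mitochondrial genes held 6.31%.

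Every table had 27996 rows for 25513 gene symbols, and the 2483 repeated rows were identical copies, so 1 row per symbol was kept. The deposited adjusted p matched Benjamini-Hochberg values over the rows whose total lay above a limit. The lowest total with an adjusted p was 52.3 for TGFβ1 in Scr cells and for siALK5 against Scr under TGFβ1, 809.7 for siALK5 against Scr without TGFβ1, and 436.4 for both other comparisons. Genes under these totals were not tested in that comparison. The log2 fold changes added up along both ways round the design within 1e-06 for 25477 of 25513 symbols.

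The threshold was an adjusted p under 0.05 as deposited. Log2 fold changes were computed from the deposited folds. Their standard errors (SE) are those implied by the deposited 2-sided p under a normal distribution, solved jointly for the 4 groups from the 5 comparisons. The squared errors along both ways round the design were equal within a relative tolerance of 0.001 for 25346 of 25346 symbols with usable p-values. For 2 genes with a p listed as 0, ADAMTS15 and SERPINE2, the error rests on the smallest p that can be stored. Group means were implied by the total and the folds, with 4 libraries per group, and are called implied means. They assume that the total is the sum of normalised counts over all 16 libraries, which the submitters do not state, and the level floor for named genes rests on the same assumption. They were checked on 524 genes by comparing the difference in variance between groups with the difference in inverse mean, for which counting error predicts a ratio of 1, and the median ratio was 1.07. The implied coefficient of variation between replicates was 17.8% at means of 10 to 100, 6.46% at 100 to 1000 and 4.04% from 1000 up. Whether ALK5 siRNA altered the TGFβ1 response was tested with the difference of both TGFβ1 log2 fold changes, its SE from the 4 group variances, and Benjamini-Hochberg adjustment over the 21088 genes tested for TGFβ1 in Scr cells.

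On simulated tables of 21088 genes for this difference, the test recovered 34% of genes changed by 0.25 (log2), 88% at 0.5, 100% at 1 and 100% at 2, with 50 genes per size. The changed genes were picked only among those whose highest implied mean was at or above the median. Recovery among genes with lower means was not simulated. Of 169 calls, 8 were false (4.73%). The simulated errors were normal with the same variances that the test used. This rate thus could not reveal standard errors that are wrong for the real data. A separate simulation for gene lists took its spread from TGFβ1 in Scr cells. Of 20 simulated lists shifted by the standard deviation of the statistic, 20 were called, and of 20 unshifted lists, 0 were called. Simulated genes were independent of each other, so false calls among genes that vary together were not tested.

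The 26 gene lists were fixed before the data were examined, as were the comparisons, the thresholds, the rule for named genes and the alternatives, apart from those named below as added. They hold 680 members, of which 634 matched a symbol of the tables directly or through an older symbol. The lists cover the TGFβ pathway, SMAD3 targets, BMP targets, contractile genes, interstitial matrix, collagen enzymes, basement membrane, matrix proteases, integrins, pericyte markers, the Notch pathway, angiogenic ligands, inflammatory genes, interferon-stimulated genes, cell cycle, hypoxia, ATF4 targets, endoplasmic reticulum chaperones, YAP and SRF targets, the Wnt pathway, cholesterol synthesis, p53 targets, and markers of endothelial cells, of astrocytes and neural cells, of microglia and leukocytes, and of perivascular fibroblasts. Each list with at least 3 tested members was compared with all other genes by cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal quantile of the deposited p, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation was not possible without values per sample, so a preset of 0.05 was used as the alternative. In every called list the median, the mean and the test had the same sign.

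The named genes are TGFBR1, the 8 largest rises and 8 largest falls of each of the 4 pairs, the 5 most negative and 5 most positive differences in response, and up to 4 members per list and comparison by size of change. All had to pass the threshold and have an implied mean, in the higher group, at or above the median of the tested genes. Where no list member did so, the 2 with the lowest adjusted p were taken. Clone names, long noncoding RNAs and small RNAs were left out. Genes of the Y chromosome and XIST, and some genes that the rule names, are not reported here.

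The alternatives were an implied mean of at least 10 or of at least 100 in the higher group, an added absolute log2 fold change of 1, an adjusted p under 0.01, adjustment over all deposited p-values, and the table of all groups. For the lists they were ranks, the log2 fold change as the statistic, a correlation of 0.05 and a mean of at least 10. Added after the data were examined were counting every row, adjusting over 1 row per symbol, and removing the trend of the fold change on transcript length and GC content, with medians of 25 bins. Length and GC were those of the longest transcript per symbol in GENCODE 29 (build GRCh38), found for 16922 of 21088 tested genes (80.2%). Since that build is not the authors' build, no coordinates are given. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.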

Results

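RNA levels were measured in human brain pericytes with a control siRNA (Scr) or an siRNA against the TGFβ receptor ALK5, each without and with TGFβ1, with 4 libraries per group. The files give comparisons between groups, not values per sample, and the depth of each sample is unknown. Fold changes are given on the log2 scale ± the standard error implied by the deposited p. Numbers of list members are given over all genes and, beside that, adjusted over the list alone. The median log2 fold change of tested genes lay between -0.01 and 0.01 in every comparison.

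TGFBR1, the gene of ALK5 and the target of the siRNA, showed how far the receptor RNA was lowered. Its log2 change was -2.02 ± 0.07 without TGFβ1 and -2.05 ± 0.07 with it, which left 24.6% (95% interval 22.4 to 27.1) and 24.1% (21.98 to 26.4) of the Scr level. The authors' deposited tables list a 4.06-fold decrease (adjusted p = 1.02e-182) and a 4.15-fold decrease (adjusted p = 2.64e-198). TGFβ1 raised TGFBR1 by 0.21 ± 0.06 in Scr cells (adjusted p = 0.00632). In siALK5 cells the change of 0.17 ± 0.07 did not pass (adjusted p = 0.386). The implied means were 2432 in Scr untreated, 2804 in Scr with TGFβ1, 599 in siALK5 untreated and 676 in siALK5 with TGFβ1.

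The comparison of TGFβ1-treated with untreated Scr cells gives the response at the control level of ALK5. The labels give 24 h in 1% serum for both treated groups and do not say whether untreated cells had it, so the comparison can hold an effect of that step. An effect alike in both arms would be kept in siALK5 cells, where most of the large responses were smaller (see the difference in response below). ESM1, which encodes the secreted proteoglycan endocan, rose most among the named genes, by 5.82 ± 0.21, a 56.3-fold increase in the authors' deposited table (adjusted p = 4.30e-168). The NADPH oxidase NOX4 rose by 4.09 ± 0.15, the tetraspanin TSPAN2 by 4.04 ± 0.23, and the Notch-related transcription factor HEYL by 3.18 ± 0.15. PRR15 (3.23 ± 0.18), PCDH10 (2.82 ± 0.07), SERPINE2 (2.77 ± 0.07) and PLXDC2 (2.74 ± 0.07) completed the 8 largest rises. IQSEC3 changed by -2.91 ± 0.12 and the homeobox factor MEOX2 by -2.57 ± 0.11. SLC7A14, FAM65C, PDE7B, HGF and C11orf87 had values from -2.51 to -2.42. In all, 5861 of 21088 tested genes passed, 3171 higher and 2690 lower. Of these, 453 were higher and 422 lower by at least 1 on the log2 scale.

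Among SMAD3 targets, genes switched on by the receptor's main transcription factor, 33 of 36 members rose and 3 fell (33 and 3 adjusted over the list alone), with a median of 1.25 (list adjusted p = 1.96e-106). JUNB rose by 2.48 ± 0.05 and PMEPA1, an inhibitor of the pathway, by 2.39 ± 0.05, with adjusted p listed as 0 for both genes. In the TGFβ pathway list 23 of 41 members rose and 5 fell (23 and 6 adjusted over the list alone; list adjusted p = 2.69e-14), among them the ligand subunit INHBA at 1.61 ± 0.06 and SKIL at 1.43 ± 0.12. YAP and SRF targets rose in 13 of 18 members and fell in 3 (14 and 4 adjusted over the list alone, list adjusted p = 1.35e-22), with ANKRD1 at 2.55 ± 0.05 and CTGF at 1.25 ± 0.03.

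Contractile genes rose in 20 of 26 members and fell in 3 (the same numbers adjusted over the list alone, list adjusted p = 1.32e-12). Tropomyosin TPM1 rose by 1.40 ± 0.04 and calponin CNN1 by 0.88 ± 0.12, while leiomodin LMOD1 changed by -0.81 ± 0.08. Of 39 interstitial matrix genes, 24 rose and 5 fell (25 and 6 adjusted over the list alone, list adjusted p = 3.74e-07), with elastin ELN at 1.44 ± 0.10, versican VCAN at 1.36 ± 0.07 and fibrillin FBN1 at 0.90 ± 0.07. Matrix proteases and their inhibitors rose in 15 of 27 and fell in 4 (16 and 4 adjusted over the list alone, list adjusted p = 2.44e-17), and integrins rose in 17 of 29 and fell in 4 (17 and 5, list adjusted p = 5.40e-08), with ITGA4 at 1.68 ± 0.07. Collagen enzymes rose in 11 of 21 and fell in 4 (12 and 4 adjusted over the list alone, list adjusted p = 0.0277), with the lysyl hydroxylase PLOD2 at 1.09 ± 0.08. This last call was lost at a correlation of 0.05 (adjusted p = 0.105) and with the log2 fold change as the statistic (adjusted p = 0.243).

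Genes of amino acid supply and protein folding rose together. Of 24 ATF4 targets, 20 rose and 0 fell over all genes and adjusted over the list alone (list adjusted p = 1.75e-20), with the amino acid transporter SLC7A5 at 1.32 ± 0.03 and CHAC1 at 1.14 ± 0.08. Endoplasmic reticulum chaperones rose in 14 of 17 members (16 adjusted over the list alone, list adjusted p = 4.24e-11), HERPUD1 by 0.80 ± 0.04 and HSPA5 by 0.59 ± 0.03. Cholesterol synthesis genes rose in 16 of 22 and fell in 1 (18 and 1 adjusted over the list alone, list adjusted p = 0.000421), a call lost with the log2 fold change as the statistic (adjusted p = 0.130).

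Genes of immune signalling fell. Of 32 interferon-stimulated genes, 20 fell and 2 rose (the same numbers adjusted over the list alone, list adjusted p = 1.16e-09), with IFIT1 at -1.97 ± 0.09 and IFITM1 at -1.54 ± 0.09. Inflammatory genes fell in 13 of 24 members and rose in 4 (15 and 4 adjusted over the list alone, list adjusted p = 0.00131), with the chemokine CCL2 at -1.85 ± 0.10 and the adhesion molecule ICAM1 at -1.24 ± 0.08. Pericyte markers fell in 9 of 19 members and rose in 2 (10 and 2 adjusted over the list alone, list adjusted p = 5.24e-05). ZIC1 was at -0.85 ± 0.03 and CD248 at -0.80 ± 0.04, while CSPG4, which encodes NG2, rose by 1.02 ± 0.05. Cell cycle genes fell in 10 of 37 and rose in 1 (the same numbers adjusted over the list alone, list adjusted p = 0.0406), with RRM2 at -0.57 ± 0.10. The cell cycle call was lost at a correlation of 0.05 (adjusted p = 0.176), with the log2 fold change (adjusted p = 0.247) and without the length and GC trend (adjusted p = 0.0516).

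Markers of other cell types also moved. Perivascular fibroblast markers fell in 7 of 13 members and rose in 0 (8 and 0 adjusted over the list alone, list adjusted p = 4.03e-10), with KIAA1199 at -1.30 ± 0.05. Astrocyte and neural markers fell in 5 of 9 and rose in 2 (the same numbers adjusted over the list alone, list adjusted p = 6.30e-05), with the glutamate transporter SLC1A3 at -1.89 ± 0.10 and SYT1 at 0.88 ± 0.09. With ranks the latter list was not called (adjusted p = 0.0590). The remaining 9 lists did not pass, with adjusted p of 0.900 for BMP targets, 0.925 for basement membrane, 0.640 for Notch, 0.0522 for angiogenic ligands, 0.447 for hypoxia, 0.846 for Wnt, 0.0682 for p53 targets, 0.568 for endothelial markers and 0.925 for microglia and leukocyte markers. Members of these lists went both ways. PDGFB rose by 1.89 ± 0.13 and PDGFC by 1.76 ± 0.06 among angiogenic ligands, while HGF was at -2.44 ± 0.20 and CXCL12 at -1.84 ± 0.08. The median and the test differed in sign for Notch, Wnt, basement membrane, endothelial and microglia lists, and the median and the mean for BMP targets and hypoxia.

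The comparison of siALK5 with Scr cells without added TGFβ1 gives the changes with the siRNA alone. Among genes past the threshold and the level floor of the naming rule, LMOD1 rose by 0.62 ± 0.07 (adjusted p = 8.66e-14), APOE by 0.53 ± 0.08 and smooth muscle actin ACTA2 by 0.52 ± 0.07. TINAGL1, CPAMD8, ADAMTS5 and PAPPA rose by 0.42 to 0.50. PODXL fell by 0.48 ± 0.06, and PLCH2, ELTD1, RET, EPHB2 and the pseudogene ASS1P9, which can share reads with ASS1, lay between -0.44 and -0.34. TSPAN2, below that floor, rose by 1.01 ± 0.26. Of 14717 tested genes, 217 passed, 139 higher and 78 lower. Only 2 rises and 1 fall, that of the siRNA target TGFBR1, reached 1 on the log2 scale, and 125 genes passed an adjusted p of 0.01.

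Contractile genes rose in 9 of 25 tested members and fell in 0 (13 and 0 adjusted over the list alone, list adjusted p = 9.44e-24), with ACTG2 at 0.37 ± 0.08 and the transcriptional coactivator MYOCD at 0.35 ± 0.09 beside ACTA2 and LMOD1. Interstitial matrix genes rose in 7 of 37 and fell in 1 (9 and 4 adjusted over the list alone, list adjusted p = 3.49e-05), with FBN2 at 0.31 ± 0.07 and COL5A3 at 0.25 ± 0.05. Basement membrane genes rose in 2 of 18 (5 adjusted over the list alone, list adjusted p = 0.000923), COL4A2 by 0.12 ± 0.03 and LAMC1 by 0.14 ± 0.04, a call lost with the log2 fold change as the statistic (adjusted p = 0.330). Hypoxia and glycolysis genes fell in 4 of 23 and rose in 0 (6 and 0 adjusted over the list alone, list adjusted p = 4.76e-06), with NDRG1 at -0.30 ± 0.06 and the glucose transporter SLC2A1 at -0.26 ± 0.07, and the call was lost with the log2 fold change (adjusted p = 0.141).

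In the TGFβ pathway list 3 of 39 members fell and 0 rose (3 and 1 adjusted over the list alone, list adjusted p = 0.000612). They were TGFBR1 itself, LTBP2 at -0.30 ± 0.07 and TGFB1 at -0.20 ± 0.05, and the call was lost with ranks (adjusted p = 0.833) and with the log2 fold change (adjusted p = 0.0875). The Notch list was called higher on 1 member of 12, NOTCH3 at 0.26 ± 0.05 (3 adjusted over the list alone, list adjusted p = 0.0353), and lost the call under all 5 alternatives, with adjusted p from 0.108 to 0.332. SMAD3 targets did not pass, with 1 of 34 higher and 1 lower (3 and 3 adjusted over the list alone, list adjusted p = 0.476). CTGF was at 0.16 ± 0.03 and LTBP2 at -0.30 ± 0.07.

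The comparison of TGFβ1-treated with untreated siALK5 cells gives the response at the lower level of receptor RNA. The treated cells had the same serum step as treated Scr cells, and the labels do not say whether untreated cells had it. ESM1 rose by 3.40 ± 0.26 (adjusted p = 2.33e-35), NOX4 by 1.97 ± 0.17, PRR15 by 1.959 ± 0.22 and TSPAN2 by 1.62 ± 0.21, all at levels below the floor of the naming rule. Above that floor, the protocadherin PCDH10 rose by 1.02 ± 0.07 (adjusted p = 1.02e-39), SERPINE2 by 0.86 ± 0.04, PLXDC2 by 0.86 ± 0.08 and JUNB by 0.82 ± 0.06. ANKRD1 (0.81 ± 0.05), GADD45B (0.80 ± 0.06) and MFAP3L (0.76 ± 0.07) also rose. The falls were smaller, with CDR1 at -0.46 ± 0.09, MEOX2 at -0.41 ± 0.09 and PDE7B at -0.40 ± 0.10, and FAT4, GPRC5A, MXRA5 and IQSEC3 between -0.36 and -0.33. Of 16156 tested genes, 276 passed, 215 higher and 61 lower, and 16 rises and 0 falls reached 1 on the log2 scale.

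SMAD3 targets rose in 18 of 35 tested members and fell in 0 (20 and 1 adjusted over the list alone), with a median of 0.28 (list adjusted p = 3.16e-77). YAP and SRF targets rose in 5 of 17 (8 higher and 1 lower adjusted over the list alone, list adjusted p = 1.44e-19) and matrix proteases and inhibitors in 6 of 24 (7 and 1, list adjusted p = 3.06e-14). ATF4 targets rose in 3 of 24 (11 adjusted over the list alone, list adjusted p = 5.24e-13), with SLC7A5 at 0.37 ± 0.04. Contractile genes rose in 4 of 25 (4 adjusted over the list alone, list adjusted p = 1.91e-09), with TPM1 at 0.36 ± 0.04, and TGFβ pathway genes in 6 of 39 (11 and 3, list adjusted p = 8.93e-08), with PMEPA1 at 0.69 ± 0.05. Among interferon-stimulated genes 1 of 25 fell, IFIT1 at -0.31 ± 0.07 (1 adjusted over the list alone, list adjusted p = 0.00239). Fibroblast markers fell in 1 of 11 (2 adjusted over the list alone, list adjusted p = 0.00104). Integrins rose in 2 of 27 (6 adjusted over the list alone, list adjusted p = 0.000580) and chaperones in 2 of 17 (3 adjusted over the list alone, list adjusted p = 0.000233). With the log2 fold change as the statistic, the integrin call (adjusted p = 0.0759), the chaperone call (adjusted p = 0.290) and the fibroblast call (adjusted p = 0.271) were lost. The basement membrane list was called lower with 0 of 20 members past the threshold (0 adjusted over the list alone, list adjusted p = 0.0290). Pericyte markers were called lower, though 1 of 15 rose and 0 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.0272). Hypoxia genes were called higher on 1 of 23 (1 adjusted over the list alone, list adjusted p = 0.0290). These lists lost their calls at a correlation of 0.05, with adjusted p of 0.117, 0.0898 and 0.117 in this order. With the log2 fold change they also lost them, with adjusted p of 0.315, 0.290 and 0.377.

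Setting siALK5 against Scr under TGFβ1 asks how far the treated cells differed with the ALK5 siRNA. SLC7A14 was higher by 2.65 ± 0.10 (adjusted p = 6.84e-155), the cation channel TRPC6 by 2.60 ± 0.09 and IQSEC3 by 2.45 ± 0.12. PDE7B, ADAMTS15 and FAM65C were higher by 2.16 to 2.17. ESM1 was at -3.15 ± 0.13, NOX4 at -2.44 ± 0.10, PLXDC2 at -2.16 ± 0.07 and SERPINE2 at -2.13 ± 0.06, and LGR6, HEYL and APCDD1L lay between -1.99 and -1.98. Of 21088 tested genes, 5323 passed, 2373 higher and 2950 lower, with 380 higher and 282 lower by at least 1.

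SMAD3 targets were lower in 31 of 36 members and higher in 2 (32 and 2 adjusted over the list alone), with a median of -0.9999 (list adjusted p = 5.70e-85). Interferon-stimulated genes were higher in 19 of 32 and lower in 2 (21 and 3 adjusted over the list alone, list adjusted p = 3.27e-10), with IFIT1 at 1.98 ± 0.09. Pericyte markers were higher in 12 of 19 and lower in 2 (15 and 2 adjusted over the list alone, list adjusted p = 5.80e-06), with ZIC1 at 0.68 ± 0.03 and desmin DES at 0.65 ± 0.07. Of 4 lists of markers of other cell types, 2 moved the same way, with perivascular fibroblast markers higher in 6 of 13 and lower in 1 (6 and 1 adjusted over the list alone, list adjusted p = 4.65e-11) and astrocyte and neural markers higher in 5 of 9 and lower in 1 (5 and 2, list adjusted p = 0.000177). Endothelial markers did not pass, with 3 of 13 higher and 4 lower (4 and 4 adjusted over the list alone, list adjusted p = 0.776). Microglia and leukocyte markers did not pass either, with 1 of 4 higher and 1 lower (2 and 1 adjusted over the list alone, list adjusted p = 0.967). Contractile genes were lower in 13 of 26 and higher in 6 (14 and 6 adjusted over the list alone, list adjusted p = 0.00616), with TPM1 at -0.96 ± 0.04 and LMOD1 at 1.32 ± 0.07. This contractile call was lost at a correlation of 0.05 (adjusted p = 0.0515), with ranks (adjusted p = 0.105) and with the log2 fold change (adjusted p = 0.335). ACTA2 at 0.09 ± 0.07 (adjusted p = 0.460) and ACTG2 at 0.14 ± 0.08 (adjusted p = 0.194), both higher with the siRNA alone, did not pass here. In all, 15 lists were called, 5 higher and 10 lower.

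Whether the response to TGFβ1 treatment differed with the ALK5 siRNA was tested with the difference between both responses, siALK5 minus Scr. NOX4 rose by 4.09 ± 0.15 in Scr and 1.97 ± 0.17 in siALK5 cells, a difference of -2.12 ± 0.22 (adjusted p = 8.03e-20). IQSEC3 changed by -2.91 ± 0.12 in Scr and -0.33 ± 0.10 in siALK5 cells, a difference of 2.58 ± 0.15 (adjusted p = 2.21e-62). The difference passed for 3070 of 21088 genes, 1340 positive and 1730 negative. Among the 291 genes that rose by at least 1 in Scr cells and were tested in both arms, 281 had the same sign in siALK5 cells and 276 had a smaller response by the test of the difference. The median share of the log2 response kept was 23.9%. Of 246 such falls, 223 had the same sign and 234 had a smaller response, with a median share of 11.4%. Over all 2982 rises and 2491 falls past the threshold in Scr cells and tested in both arms, the median shares were 18.03% and 13.3%, which lie closer together.

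**Figure D1:**
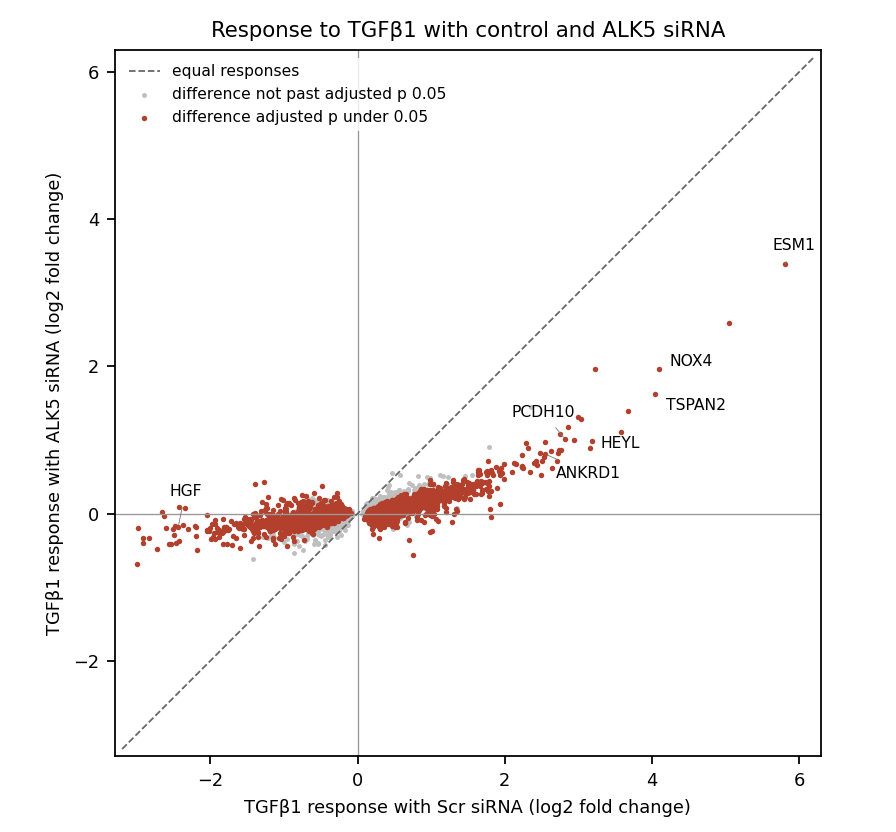
Log2 fold change by TGFβ1 with the Scr siRNA (horizontal) and with the ALK5 siRNA (vertical) for each gene past adjusted p 0.05 in Scr cells and tested in both arms, with genes whose responses differed in red. Most points lie nearer the horizontal axis than the dashed line of equal responses.

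**Figure D2:**
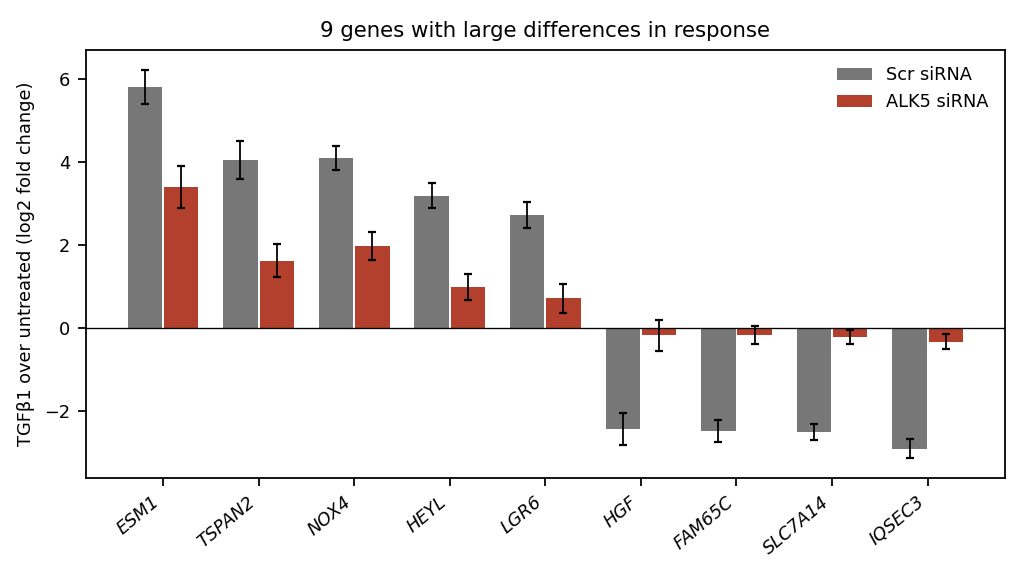
Log2 fold change by TGFβ1 with the Scr siRNA (grey) and the ALK5 siRNA (red) for 9 genes with large differences, with bars for 95% intervals from the implied standard errors. ESM1 rose by 5.82 with Scr and by 3.40 with ALK5 siRNA.

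**Figure D3:**
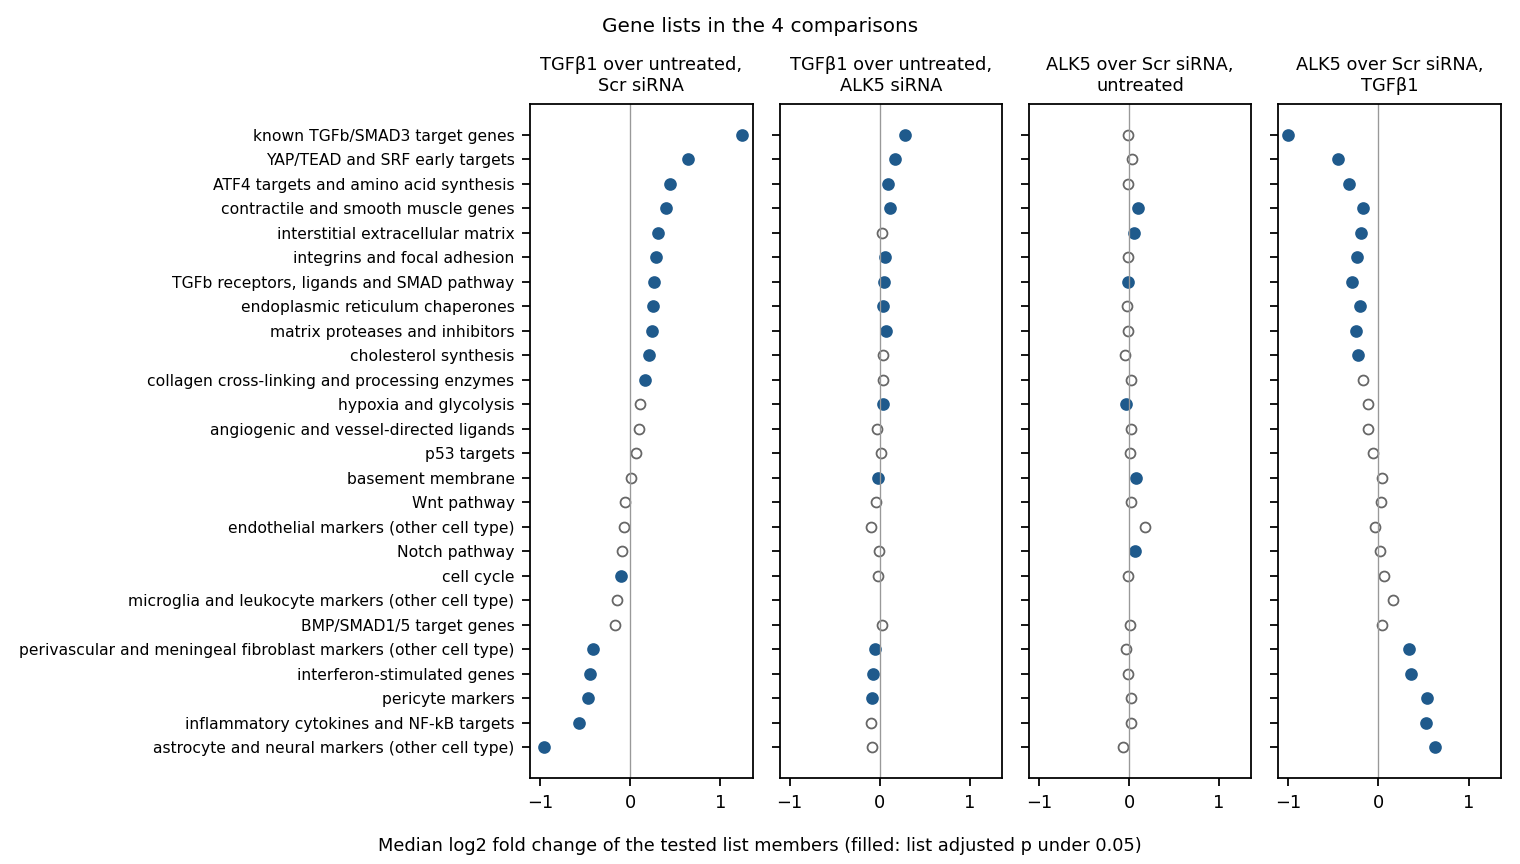
Median log2 fold change of the tested members of each gene list in the 4 comparisons, with filled points for lists with an adjusted p under 0.05. SMAD3 targets had a median of 1.25 for TGFβ1 with the Scr siRNA and 0.28 with the ALK5 siRNA.

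The authors' deposited table of all groups also sets siALK5 with TGFβ1 against Scr untreated. In it 676 of 16156 tested genes passed, 455 higher and 221 lower, and 15 rises and 1 fall, that of TGFBR1, reached 1 on the log2 scale. ESM1 was 6.36-fold higher (adjusted p = 4.76e-31) and TGFBR1 3.597-fold lower (adjusted p = 1.64e-157) in that table.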

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

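Of the tests in this part, that of a common shift of the libraries was chosen only after the result was seen. The TGFβ1 response differed between siALK5 and Scr cells, by the test of the difference itself, for 3070 genes. Among the named genes the difference in log2 response, siALK5 minus Scr, was most negative for TSPAN2 (-2.42), ESM1 (-2.42), HEYL (-2.20), NOX4 (-2.12) and LGR6 (-2.00), all of which rose with TGFβ1 in Scr cells. It was positive for IQSEC3 (2.58), FAM65C (2.31), SLC7A14 (2.29) and HGF (2.26), all of which fell. Untreated levels enter these differences. The untreated implied means of TSPAN2 were low, at 20.9 in Scr and 41.9 in siALK5 cells, as were those of ESM1, at 17.2 and 10.4.

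The same test passed for 15 gene lists. The median difference was negative for SMAD3 targets (-0.92), YAP and SRF targets (-0.38), contractile genes (-0.34), ATF4 targets (-0.34), TGFβ pathway genes (-0.25), interstitial matrix (-0.24), integrins (-0.24), endoplasmic reticulum chaperones (-0.22), matrix proteases (-0.21) and cholesterol synthesis (-0.18). It was positive for astrocyte and neural markers (0.70), inflammatory genes (0.51), interferon-stimulated genes (0.47), perivascular fibroblast markers (0.35) and pericyte markers (0.32). With the log2 fold change as the statistic the chaperone call (adjusted p = 0.0613) and the cholesterol call (adjusted p = 0.211) were lost. With ranks the astrocyte and neural call was lost (adjusted p = 0.0579). For contractile genes the median change with the ALK5 siRNA was 0.10 without TGFβ1 and -0.17 with it. Their smaller response thus holds a higher untreated level as well as a lower level under TGFβ1.

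Genes that rose with TGFβ1 by at least 1 (log2) in Scr cells kept a median of 23.9% of their log2 response in siALK5 cells. Genes that fell by as much kept 11.4%, a difference of 12.5 percentage points (95% interval 10.98 to 14.3). This interval, like those of kept shares, list medians and slopes below, came from 1000 draws that resampled genes or pairs of genes. Such intervals do not hold the spread between libraries. Over all called rises and falls the shares lay closer together, at 18.03% and 13.3%. Selection and noise that is independent between genes do not alone account for the difference among genes changed by at least 1. In 200 simulated draws with 1 common share the difference was at most 2.51 points. The errors were drawn for each gene on its own, so noise shared by many genes was not tested. A common shift of the libraries would need 0.0899 on the log2 scale, but in the 2691 rises and 2245 falls under 1 its removal turned the difference from 3.14 points (2.28 to 4.38) to -54.3 (-56.4 to -52.1), where a common shift requires about 0. In 213 pairs of rises and falls matched on total and fold size the difference was 10.95 points (8.93 to 13.3), so level and fold size do not account for all of it. No biological explanation was tested, and an effect of the serum step on the part of the response that was kept was not excluded, so the cause is left open.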

How the results depend on the processing

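Counting every row, adjusting over 1 row per symbol and removing the length and GC trend were tests chosen only after the results were seen. No paired analysis was possible because the files hold no values per sample, so the replicate number in the labels could not enter a model. For the same reason leaving out each replicate, other splits of the samples, DESeq2 or edgeR fits, other size factors, a pseudocount, fits of single pairs of groups and an estimated inter-gene correlation were not run. The table of all groups gave no count for siALK5 against Scr under TGFβ1 or for TGFβ1 in siALK5 cells, since it lacks their p-values. For TGFβ1 in Scr cells and for siALK5 without TGFβ1 it held the same folds and p-values for all 25513 symbols. Its unchanged counts, also for the difference in response, were thus fixed in advance and are no test of robustness.

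With an added absolute log2 fold change of 1, the counts were 875 for TGFβ1 in Scr cells, 3 for siALK5 without TGFβ1, 662 for siALK5 under TGFβ1, 16 for TGFβ1 in siALK5 cells and 492 for the difference in response. At an adjusted p under 0.01, siALK5 without TGFβ1 gave 125 genes. These follow from the stricter thresholds. With the log2 fold change as the statistic, 2 lists were called for siALK5 without TGFβ1 and 7 for TGFβ1 in siALK5 cells; the cause was not tested. The other counts stayed within 1.5 times their values under the alternatives run. With the trend removed, TGFBR1 kept its direction and its side of the threshold in the 4 comparisons. Its directions from the table of all groups were the same but were fixed in advance, since the folds add up round the design. No result reversed. Among values of named genes, 8 no longer passed when adjusted over all deposited p-values, 3 at a mean of at least 10, and 8 with the length and GC trend removed, where 2 others passed. Among list tests, 17 calls were lost with the log2 fold change, 7 at a correlation of 0.05, 5 with ranks (4 gained), 1 at a mean of at least 10 (1 gained) and 4 with the trend removed (2 gained). The test of the difference recovered 34% of simulated genes changed by 0.25, all with a highest implied mean at or above the median. Smaller differences in response were thus often not detectable, and recovery among genes with lower means was not simulated.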

Other observations

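Of the tests in this part, those of the symbol families, of a basal ALK5 signal, of double-stranded RNA, of the siALK5 untreated libraries and of removing the length and GC trend were chosen only after the results were seen. Among 79 families of at least 15 genes that share the letters of their symbol, phosphodiesterases (PDE), most of which break down cyclic nucleotides, fell with TGFβ1 in Scr cells in 10 of 16 members and rose in 2 (family adjusted p = 0.000348). PDE7B was at -2.46, PDE4B at -1.95, PDE1A at -1.14 and PDE5A at -0.89. The difference in response, siALK5 minus Scr, had a median of 0.23 (family adjusted p = 0.00225). Krüppel-like transcription factors (KLF) rose in 7 of 15 and fell in 4 (family adjusted p = 0.0291), with KLF4 at 1.03, KLF7 at 1.01 and KLF2 at 0.80. Secretory pathway genes (SEC) rose in 13 of 27 and fell in 3 (family adjusted p = 0.0443). Keratins (KRT) rose in 17 of 22 and fell in 0 (family adjusted p = 2.64e-11), but most were pseudogenes that can share reads with KRT18, at 0.99. KRT7 was at 1.38 and KRT80 at 0.64, while KRT8 at -0.12 did not pass.

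The contractile list was called higher with the ALK5 siRNA without TGFβ1, with 9 of 25 members higher past the threshold, 0 lower and a median of 0.10. Loss of a basal ALK5 signal that acts as added TGFβ1 does would lower genes that TGFβ1 raises. The list rose with TGFβ1 in Scr cells too, with a median of 0.40 (0.25 to 0.58, from resampling members) over all 25 members. With TGFβ1, 20 members were higher past the threshold and 3, among them LMOD1, lower. Both comparisons share the Scr untreated group, so a low level there would raise the list in both. Against that group, siALK5 with TGFβ1 was also higher in 17 of 25 members and lower in 0. The list adjusted p was 1.32e-40, with 22 and 0 adjusted over the list alone. This comparison adds up from the siRNA alone and TGFβ1 in siALK5 cells, where the list was called higher in both. It is thus no separate test of a low level in Scr untreated cells. The TGFβ1 comparison can also hold the serum step. The values thus speak against such a loss for this list as a whole, and only if neither plays a part. Of the 9 members that rose with the siRNA, 7 were higher with TGFβ1 in Scr cells and 1, LMOD1, was lower. Genes outside the list were not tested for such a loss. After the length and GC trend was removed the median was 0.098 (0.0622 to 0.231), against 0.101 before. Both groups received the same siRNA dose, so a general response to double-stranded RNA would cancel and the median of -0.0153 for interferon-stimulated genes decides nothing about it. An effect of the siRNA on other transcripts may contribute and stays untested, as does a direct effect of the lower ALK5 level.

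Long transcripts were slightly lower in siALK5 cells with TGFβ1 than without, by a slope of -0.042 on the log2 scale per 10-fold length (-0.048 to -0.036) over 11923 genes with a mean of at least 100 per library. The intervals of the slopes came from resampling genes and do not hold the spread between libraries. Among 2544 of these genes with an unadjusted p above 0.5 for TGFβ1 in Scr cells the slope was -0.024 (-0.037 to -0.0096), which argues against long TGFβ1-responsive genes as the whole cause. Against Scr untreated the slope of siALK5 with TGFβ1 in these genes was -0.036 (-0.047 to -0.025), which argues against a property of the siALK5 untreated libraries alone. Quality of RNA or libraries in the siALK5 group with TGFβ1 may contribute and could not be tested without values per sample.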
